A study of Mus musculus with 9 samples.

How the data were processed

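RNA was measured in 9 libraries of mouse bone marrow-derived macrophages in 3 groups of 3: wild-type (WT) cells at 0 h, WT cells after 24 h with oxidized low-density lipoprotein (ox-LDL) and cells without MKP5 (MKP5-KO) after 24 h with ox-LDL. Groups came from the sample labels, and genotype and hours in the file headers matched them in all 9 libraries. Total RNA was extracted with a Qiagen RNeasy kit, 1 µg went into each library, and a sequencing company (Genewiz/Azenta) made the libraries, per the labels' protocols. Reads were aligned with STAR to the mouse genome GRCm39, per the submitters' processing notes. The STAR version, the gene annotation, the counting tool, its use of strand and its treatment of reads that match several genes are not given in the sources used here. Members of families of near-identical genes (Ly6c2, Pira2, the histones, the ribosomal proteins and the MHC class II genes among them) and genes that overlap others on either strand are therefore uncertain to the extent that reads were split between them.

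Each file held 1 value per gene for 56775 genes, log2 normalized counts scaled by a TMM factor, per the file headers. The deposited log2 values followed log2 of reads plus 0.5, divided by gene length, plus a constant for each library. This was checked by turning the values back into reads with exon lengths from the GENCODE M21 annotation: 87.6% of the genes with few enough reads to test came out as whole reads, with a tolerance of 0.004 reads. A further 3212 genes gave whole reads at a fitted length, and 357 had too many reads for the check. In all 9 libraries 30607 genes sat at the value that 0 reads give. M21 is built on an earlier assembly than the one the submitters used, so it served for names, lengths and neighbouring genes, and no coordinates are printed. Expression levels are given as CPM, recovered reads in counts-per-million units of the TMM-scaled library size, as mean ± SD. The 13 mitochondrially encoded mRNAs were listed at 0 reads in every library and were not analysed here.

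A count-based quasi-likelihood test had been chosen before the data were examined, for the case of deposited counts. Because the deposited values are log2 values, limma was used on them in its place, the test named for that case. The groups, comparisons, gene lists, rule for named genes and most of the alternative settings were also fixed before the data were examined. Genes with at least 10 reads at the median depth in at least 3 libraries and at least 15 reads in total were tested, 14794 in all, and 224 of them had no reads in at least 1 library. One model with a mean per group was fitted over all 9 libraries (limma 3.58.1, R 4.3.3, statmod 1.5.0, empirical Bayes moderation with a mean-variance trend and the robust option). The 2 comparisons were WT at 24 h against WT at 0 h and MKP5-KO against WT at 24 h. Tests were two-sided, adjusted p-values follow Benjamini and Hochberg over the tested genes, and the threshold was 0.05 with no minimum fold. Log2 fold changes are on the deposited scale with its 0.5 reads, which understates changes of genes with few reads. Where a group had 0 to 3 reads of a gene in all, the ratio of reads with its 95% exact interval, or a bound from a floor of 3 reads per group, replaces the fitted fold. Such intervals cover counting error only. Figures and read recovery used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

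Of 646 different genes in 38 gene lists, 645 were found in the files, 3 of them through a synonym. Some genes are in several lists, so the lists are not independent. In all, 33 lists had at least 5 tested members. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over lists, and again with an estimated correlation and with fry. With the estimated correlation no list passed the threshold in either comparison. Members past the test were counted over all genes tested and adjusted over the list alone. Named genes were the target gene Dusp10, the 10 largest rises and falls per comparison among called genes with at least 5 CPM on average and groups that do not overlap (predicted genes and clones left out), up to 4 members with the smallest p per described list, 5 genes per direction pair of the overlap, sex-linked genes, and cell type markers at 5 CPM or more. Members behind counts of 5 or fewer that fall outside this rule were named after their values were seen. Some genes that these rules would name are not reported here.

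Depth ran from 11114225 to 19818115 recovered reads. Tested on simulated data with known folds, the model recovered 59.1% of 1.5-fold, 79.7% of 2-fold and 96.9% of 4-fold changes for ox-LDL, and 55.2%, 75.8% and 97% for MKP5 deletion. It called 9 and 6 of 14594 unchanged genes. The simulations left 14594 of 14794 genes unchanged and held the library scaling fixed, whereas the data gave 8189 and 4230 calls. Recovery and false calls in the 2 comparisons themselves may therefore differ from these values. Replicates of a group differed by more than counting noise in every pair (chi-square per degree of freedom 2.25 to 9.8), so none was treated as a duplicate. The labels do not say that replicates are separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. The labels name no sequencing batches. Alternatives covered scaling, test, filter, samples in the fit, a replicate block, thresholds, pseudocount, depth and leaving out each library; the closing section gives their effect.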

Results

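RNA sequencing was carried out on macrophages grown for 7 days from C57BL/6 mouse bone marrow in medium with 15% supernatant of L-929 cells, a fibroblast line that supplies the growth factor M-CSF. The cells were WT or lacked MKP5, a dual-specificity phosphatase encoded by Dusp10 that dephosphorylates stress-activated MAP kinases. Ox-LDL, a modified lipoprotein that macrophages take up in atherosclerotic plaques, was given at 20 µg/mL. The 3 groups were WT at 0 h, WT after 24 h and MKP5-KO after 24 h, with 3 libraries each. Recovered reads numbered 15721068, 17175552 and 16168890 in WT at 0 h, 17402858, 18689931 and 19818115 in WT at 24 h, and 11114225, 13383376 and 14335101 in MKP5-KO. MKP5-KO cells at 0 h and WT cells kept for 24 h without ox-LDL were not analysed here. The first comparison therefore joins ox-LDL with additional time in culture, and the genotype comparison holds for treated cells only.

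The first principal component of the log2 values held 61.2% of the variance and placed the WT 0 h libraries between 75.6 and 80.6 and the 24 h libraries of both genotypes between -42.8 and -34.7. The second, with 17.1%, placed WT at 24 h between -38.3 and -26.8 and MKP5-KO between 28.6 and 48.5. On the third, with 5.9%, MKP5-KO replicate 1 lay at 33.3 and the other MKP5-KO libraries at -18.9 and -28.3.

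**Figure D1:**
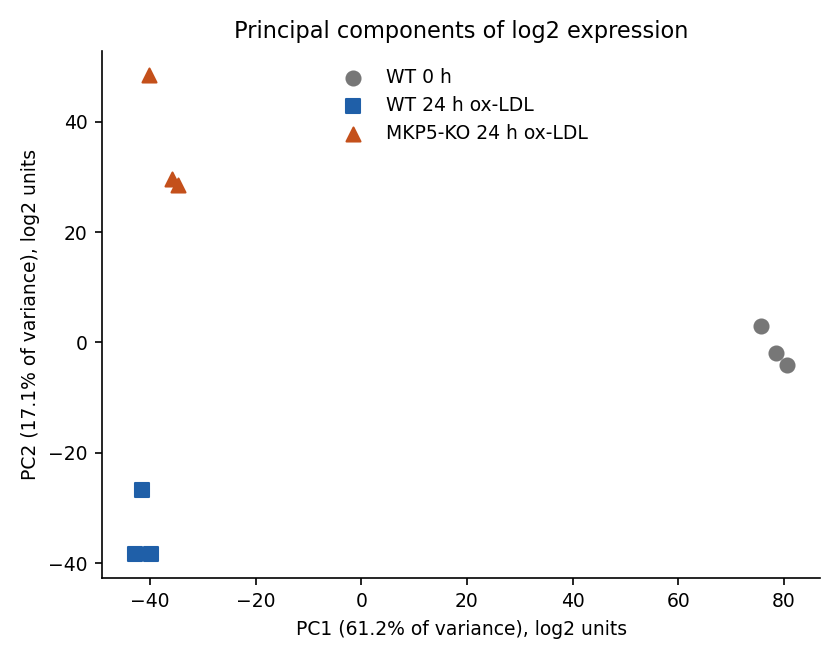
Each point is 1 library, placed by its first and second principal components of log2 expression (axes in log2 units, with the share of variance), with shape and colour for the group. WT 0 h libraries lie at 75.6 or more on the first axis, and the second axis places MKP5-KO at 28.6 or more and WT at 24 h at -26.8 or less.

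The target gene Dusp10 had 41, 48 and 44 reads in WT at 0 h, 43, 38 and 40 in WT at 24 h, and 4, 6 and 4 in MKP5-KO. Its level was 2.36 ± 0.122, 1.87 ± 0.2 and 0.307 ± 0.0739 CPM (SD, n = 3). Dusp10 was 5.66-fold lower in MKP5-KO than in WT at 24 h (log2 fold change -2.50, SE 0.26, adjusted p = 9.52e-05). Between 0 h and 24 h in WT the difference of -0.33 did not pass the test (adjusted p = 0.304).

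The first comparison asked what changed in WT macrophage cultures after 24 h with ox-LDL. Transcripts of the extracellular matrix were among the largest rises: Col1a1, a chain of type I collagen, went from 0.372 ± 0.089 to 36.3 ± 5.95 CPM (SD, n = 3; log2 fold change 6.52, SE 0.543, adjusted p = 2.28e-06), and Fn1, which encodes fibronectin, from 4.6 ± 0.976 to 154 ± 20.9 CPM (5.07, SE 0.183). The monocyte-attracting chemokine Ccl2 fell from 369 ± 36.2 to 2.5 ± 0.816 CPM (-7.24, SE 0.407, adjusted p = 1.3e-07) and its relative Ccl7 from 218 ± 33.8 to 0.627 ± 0.288 CPM (-8.48, SE 0.541). Irf7, a transcription factor of the interferon response, fell from 545 ± 34.8 to 40.4 ± 6.09 CPM (-3.76, SE 0.19). For each of these genes all 3 libraries of one group lay beyond all 3 of the other.

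The other largest rises were Adgre4, an adhesion receptor of macrophages (log2 fold change 6.34), the matrix genes Tnc (6.24), Col12a1 (6.01), Col1a2 (5.54) and Bgn (4.90), Plxdc2 (5.67), the prostaglandin-degrading enzyme Hpgd (5.01) and Gprc5c (4.82). The other largest falls were those of Plac8, S100a9, Ltf, Ly6c2, Ngp, Chil3, Slfn4 and Padi4. The log2 fold change was -8.78 for the monocyte antigen Ly6c2, -8.61 for the granule protein Ngp, -8.16 for Chil3, -7.86 for Slfn4 and -7.59 for Padi4, an arginine deiminase of granulocytes. Plac8 had 1479 reads at 0 h and 2 at 24 h, an 850-fold lower level with a 95% exact interval of 235 to 7030 for counting error. The calprotectin subunit S100a9 had 1646 and 3 reads, 631-fold lower (216 to 3060), and the lactoferrin gene Ltf 1174 and 2 reads, 675-fold lower (186 to 5580).

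Of 14794 tested genes, 8189 changed, 4048 higher and 4141 lower; 2514 of them changed at least 2-fold, 1339 higher and 1175 lower. The split depended on scaling, with 4936 higher and 3557 lower under upper-quartile factors. Groups did not overlap for 64% of tested genes, where chance gives 10%. The list counts that follow are over all genes tested, and counts adjusted over the list alone were identical unless given.

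**Figure D2:**
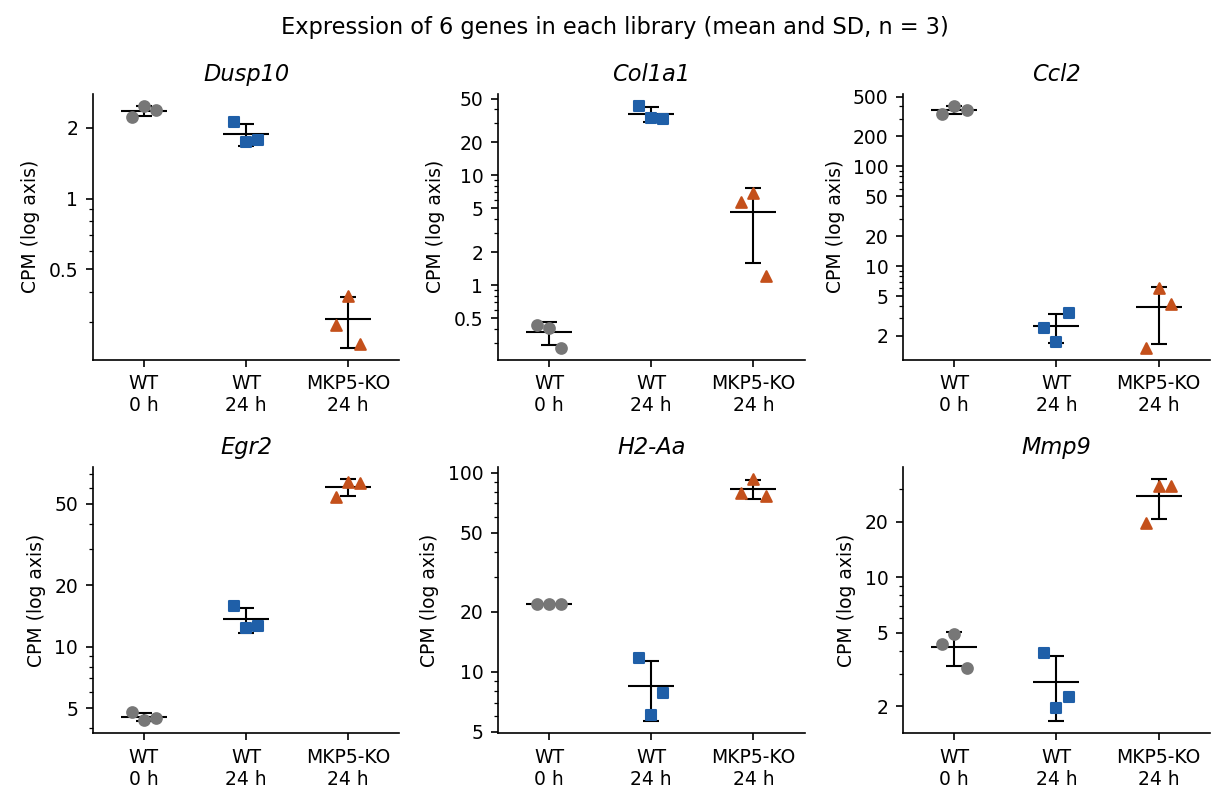
Levels of 6 genes (CPM, log axis) in each library, with 3 points per group, the group mean as a horizontal mark and the SD as a bar (n = 3). Dusp10 lies at 0.387 CPM or less in the MKP5-KO libraries, Col1a1 and Ccl2 differ most between WT at 0 h and 24 h, and H2-Aa, Mmp9 and Egr2 are higher in MKP5-KO than in WT at 24 h.

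Genes of cholesterol synthesis and LDL uptake, targets of the transcription factor SREBP2, fell in 23 of 24 cases (24 adjusted over the list alone), with a median log2 fold change of -1.80. The log2 fold change was -2.57 for Cyp51, an enzyme of the sterol pathway, and -2.04 for its regulator Insig1. The list passed camera with adjusted p = 3.6e-14, and adjusted p = 0.078 with an estimated correlation. Among LXR target genes for cholesterol efflux, 7 of 12 rose, among them the exporter Abca1 (177 ± 11.2 to 944 ± 128 CPM, 2.41) and Apoe (698 ± 21.4 to 3788 ± 892 CPM, 2.42). The 3 that fell were Scd2 (-3.49), Srebf1 (-0.84) and Lpcat3 (-0.65), the last pair named after their values were seen, and camera did not call the list (adjusted p = 0.13).

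Interferon-stimulated genes fell in 26 of 28 cases, with a median of -2.23; Isg15, a ubiquitin-like modifier, went from 157 ± 15 to 9.08 ± 1.55 CPM (-4.11) and the virus-tethering protein Bst2 fell (-2.24). Irf1 was the 1 member that rose (0.65; named after its value was seen). For this list camera gave adjusted p = 9.9e-13, and adjusted p = 0.23 with an estimated correlation. Of the NF-kB cytokines and regulators 12 of 24 fell and 9 rose, and camera did not call the list (adjusted p = 0.24). Tnf fell from 24.7 ± 0.623 to 5 ± 0.561 CPM (-2.31), and Ccl4 (-3.59) and the interleukin-1 receptor antagonist Il1rn (-3.16) fell too.

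In the integrated stress response and amino acid synthesis list 16 of 18 genes fell and none rose (median -2.27): Phgdh, the first enzyme of serine synthesis, went from 87.9 ± 2.29 to 2.86 ± 0.251 CPM (-4.94), the amino acid transporter Slc7a5 changed by -3.77 and the transcription factors Ddit3 and Atf4 by -3.31 and -1.93. All 18 endoplasmic reticulum chaperone genes fell (median -0.95), with Hspa5 from 2101 ± 147 to 591 ± 23.7 CPM (-1.83) and Hyou1 at -1.96. All 21 glycolysis and hypoxia genes fell (median -0.79), among them Ldha (-1.20), the lactate exporter Slc16a3 (-2.19) and Pfkp (-1.87). Of the heat shock proteins 12 of 13 fell, with Hspd1 at -1.27 and Hsp90aa1 at -1.50; Hspb1 rose (1.93; named after its value was seen), a call lost in 8 of 18 alternatives with adjusted p up to 0.13. These lists had camera adjusted p = 1.5e-10, 5.2e-11, 1.5e-10 and 0.00013 in this order. With an estimated correlation they had adjusted p = 0.078, adjusted p = 0.11, adjusted p = 0.099 and adjusted p = 0.078.

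Immediate early and AP-1 genes fell in 13 of 21 cases (14 adjusted over the list alone), with Myc at -3.01 and Klf4 at -2.73, and rose in 5, Egr2 (1.57), Junb, Fosl2, Fos and Zfp36, of which all but Egr2 were named after their values were seen. Of 13 genes in the MAP kinase phosphatase list, which holds Dusp10, 6 fell, among them Dusp4 (-2.93) and Dusp6 (-1.92). Dusp22 rose (0.41, named after its value was seen). Both lists passed camera, with adjusted p = 0.039 and 0.02, and adjusted p = 0.24 and adjusted p = 0.16 with an estimated correlation. The AP-1 call was lost at equal depth and without WT 24 h replicate 2, with adjusted p up to 0.054. NRF2 targets fell in 11 of 25 cases, Slc7a11 at -3.50 and Sqstm1 at -1.74 among them, and Taldo1, Blvrb, Cat, Gclm and Ftl1 rose, all but Taldo1 named after their values were seen (Ftl1 lost its call without WT 0 h replicate 1, adjusted p = 0.05; list camera adjusted p = 0.022, adjusted p = 0.56 with an estimated correlation).

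Matrix remodelling genes rose in 17 of 24 cases (18 adjusted over the list alone; median 1.25). The elastase Mmp12 went from 77.1 ± 6 to 810 ± 147 CPM (3.38), the growth factor Pdgfb rose by 2.43 and Tgfbr1 by 1.68. Spp1, Plau, Plaur and Adam8 fell (named after their values were seen), and with adjustment over the list alone 5 fell. The remodelling list had camera adjusted p = 4e-04, and adjusted p = 0.092 with an estimated correlation. Stromal fibroblast markers rose in 10 of 11 cases (median 4.49, adjusted p = 0.00013, and adjusted p = 0.24 with an estimated correlation): Postn had 1 read at 0 h and 598 at 24 h, 520-fold higher with an exact 95% interval of 93 to 20600, and Acta2 rose by 4.49. The remaining marker, Pdgfra, stood at 0.663 ± 0.318 and 0.51 ± 0.164 CPM.

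Genes for the uptake of dead cells rose in 13 of 19 cases (median 0.62): Mertk went from 39.9 ± 3.34 to 160 ± 15.9 CPM (2.00), its ligand Pros1 changed by 2.00 and the integrin Itgb5 by 1.83. Axl (-0.60) and Elmo1 (-0.44) fell, named after their values were seen. As a list they had camera adjusted p = 0.00035, and adjusted p = 0.19 with an estimated correlation. Chemokine receptor and adhesion genes rose in 9 of 15 cases, with the integrins Itgal (18.8 ± 0.553 to 207 ± 6.19 CPM, 3.46) and Itgax (3.50) and the receptor Cxcr4 (2.39), and 3 fell, among them Ccr2, the receptor of Ccl2 (304 ± 5.95 to 36.4 ± 3.46 CPM, -3.07), and Itgb1 (-0.14). Itgb1 was named after its value was seen and lost its call in 9 of 18 alternatives with adjusted p up to 0.35. The list passed with camera adjusted p = 0.0081, and adjusted p = 0.11 with an estimated correlation.

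Markers of other cells moved with these groups. Of 11 neutrophil markers 9 fell with a median log2 fold change of -6.61 over the list, -5.95 with genes of few reads at their bound (camera adjusted p = 0.0011, adjusted p = 0.078 with an estimated correlation). Camp and Elane had 112 and 126 reads at 0 h and 0 at 24 h, at least 42.9-fold and 48.3-fold lower, while Mmp8 (1.33) and Csf3r (0.61) rose. Whether the falls came from a smaller share of such cells at 24 h or from changes within cells was not tested. Of 15 macrophage and monocyte markers 9 rose (10 adjusted over the list alone), among them lysozyme, Lyz2 (3025 ± 31.4 to 10890 ± 1080 CPM, 1.84), and Adgre1, which encodes F4/80 (1.32). The 5 that fell were Ccr2, Ly6c2, Fcgr1, Cd14 and Cd68. The list had a median of 0.61 and a mean of -0.18, and camera, with direction up, did not call it (adjusted p = 0.09; called without any 1 WT 0 h library, adjusted p from 0.035 to 0.12 over 12 alternatives). Of 12 MHC class II and co-stimulation genes Cd40 (-2.36), H2-Eb1 (-2.01), H2-Aa (-1.41), H2-Ab1 (-1.31) and Cd86 (-0.93) fell and Cd83 (1.30), H2-DMa (0.74) and Ciita (0.75) rose, and camera did not call the list (adjusted p = 0.44); H2-Aa, H2-Ab1, Cd86 and Ciita were named after their values were seen.

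Cytosolic ribosomal protein genes rose in 14 of 28 cases with a median of 0.14 (15 adjusted over the list alone), and histone genes in 4 of 7, H2bc4, H1f2, H2bc8 and H2bc6. In camera they had adjusted p = 0.02 and 0.039, and adjusted p = 0.62 and adjusted p = 0.17 with an estimated correlation; both calls were lost without WT 0 h replicate 3, the histone call also with upper-quartile scaling, with adjusted p up to 0.05 and 0.074.

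**Figure D3:**
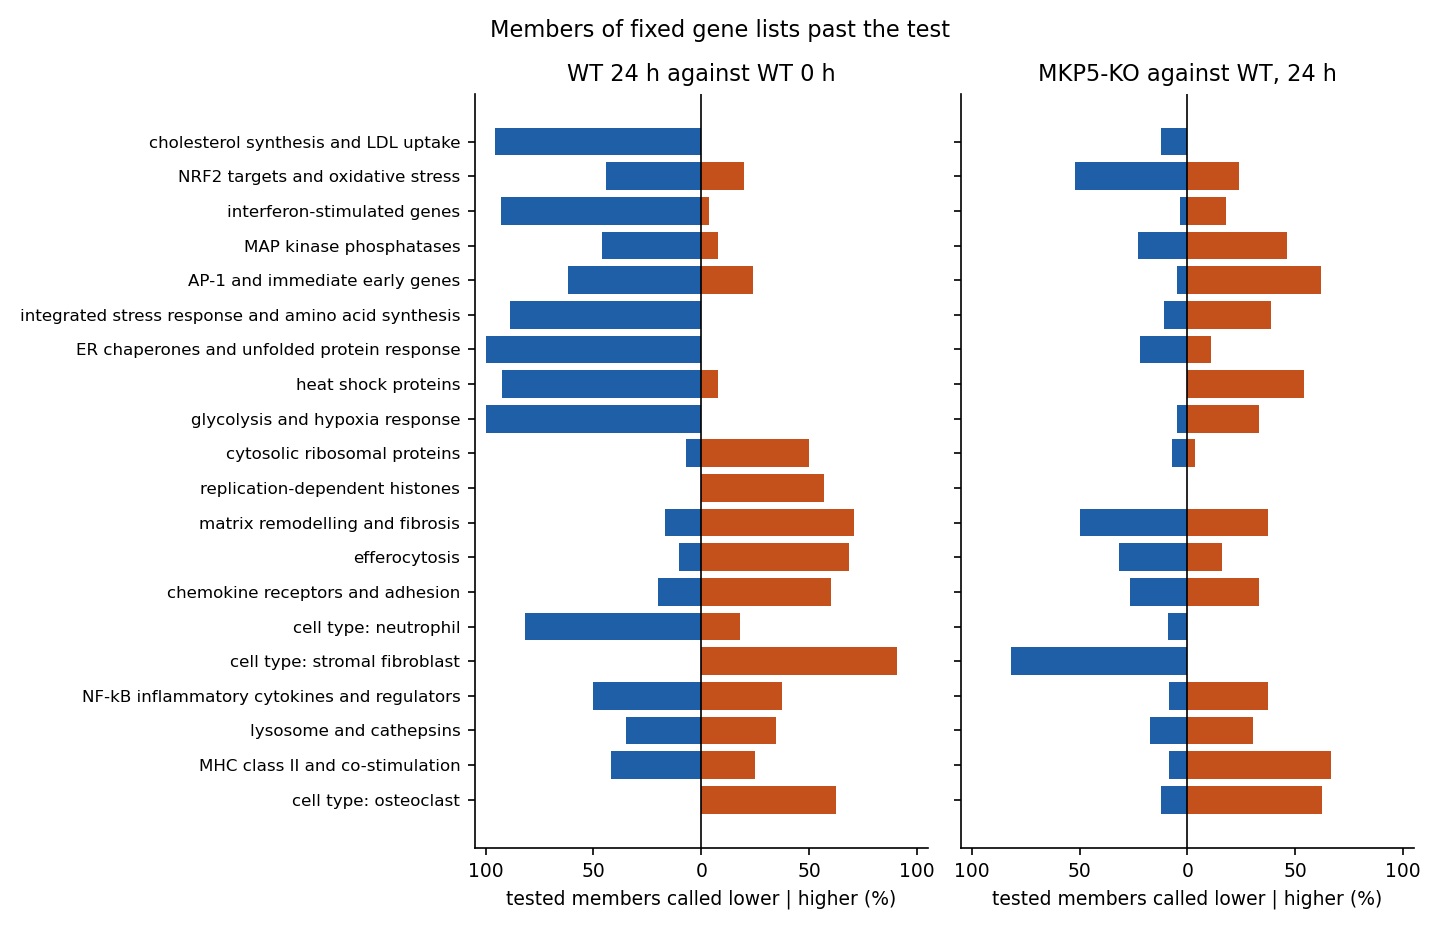
Bars give the share of each list's tested members called higher (right) or lower (left), in percent, for WT at 24 h against 0 h and for MKP5-KO against WT at 24 h; lists called by camera in either comparison are drawn. All 21 glycolysis and hypoxia genes fell in WT, where 7 were higher and 1 lower in MKP5-KO.

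The genotype comparison asked how the transcriptome of ox-LDL-treated macrophage cultures differs without MKP5. Genes for antigen presentation on MHC class II were among the largest increases: H2-Aa stood at 82.5 ± 8.99 CPM in MKP5-KO and 8.53 ± 2.87 in WT (SD, n = 3; log2 fold change 3.32, SE 0.187, adjusted p = 4.63e-06), and the invariant chain gene Cd74 at 396 ± 42.4 and 63.8 ± 21.9 CPM (2.68, SE 0.184). The gelatinase Mmp9 stood at 27.4 ± 6.6 against 2.72 ± 1.05 CPM (3.36, SE 0.274) and Dcstamp, a fusion receptor of osteoclasts and giant cells, at 132 ± 4.83 against 18.1 ± 5.97 CPM (2.91, SE 0.189). Among the largest decreases, Col1a1 stood at 4.6 ± 3 against 36.3 ± 5.95 CPM (-3.29, SE 0.543, adjusted p = 0.0017) and the smooth muscle actin gene Acta2 at 1.45 ± 1.05 against 15.6 ± 1.89 CPM (-3.88, SE 0.656). For each of these genes all 3 libraries of one genotype lay beyond all 3 of the other.

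The other largest increases were H2-Eb1 (3.54), H2-Ab1 (2.96), Fam78b (2.60), Lrrc32, which presents latent TGF-beta (2.30), the glypican Gpc1 (2.19) and the G protein regulator Rgs1 (2.18). The other largest decreases were Bgn (-3.57), Col1a2 (-3.00), Col12a1 (-2.78), Tspan32 (-2.54), Samd4 (-2.31), Gypc (-2.22), Sparc (-2.19) and Prrg4 (-2.18).

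Of 14794 tested genes 4230 differed, 1739 higher and 2491 lower in MKP5-KO, and 821 differed at least 2-fold, 564 higher and 257 lower. Groups did not overlap for 44.9% of tested genes, where chance gives 10%. This split also depended on scaling: with relative log expression factors 2012 were higher and 2064 lower, and with upper-quartile factors 2123 and 2023. Without WT 24 h replicate 2 or 3 fewer genes were called, 1637 or 1655 lower and 1186 or 1241 higher. The share of calls that were higher was then 42% or 42.9%, against 41.1% in the main fit. The MKP5-KO libraries were also the shallowest.

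AP-1 and immediate early genes were higher in 13 of 21 cases (median 0.45). Egr2 stood at 60.3 ± 5.62 against 13.6 ± 1.87 CPM (2.15), Myc at 17.7 ± 1.94 against 5.66 ± 0.348 CPM (1.64), and Fos and Atf3 differed by 1.18 and 1.13; all encode transcription factors induced by MAP kinase signalling. Ier3 was lower (-0.72; named after its value was seen). The list had the smallest camera p of this comparison, adjusted p = 2e-08, and adjusted p = 0.066 with an estimated correlation. Of the 13 genes in the MAP kinase phosphatase list 6 were higher (9 adjusted over the list alone). Among them were Dusp1 (61.4 ± 3.12 against 32.6 ± 4.01 CPM, 0.92), Dusp4 (1.16) and Dusp3 (0.35). The 3 lower were Dusp10, Dusp22 (-0.49) and Dusp7 (-0.44), the last pair named after their values were seen. Camera did not call this list (adjusted p = 0.059) but did in 6 of 12 alternatives, with adjusted p from 0.033 to 0.11.

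In the MHC class II and co-stimulation list 8 of 12 genes were higher and Cd80 was lower (-0.77; named after its value was seen; median of the list 0.56). Cd80 lost its call without MKP5-KO replicate 1 or WT 24 h replicate 3, with adjusted p up to 0.069. Ciita, the master regulator of class II transcription, stood at 18.9 ± 1.04 against 5.32 ± 0.766 CPM (1.84). By camera the list had adjusted p = 1e-05, and adjusted p = 0.38 with an estimated correlation. Of 5 tested dendritic cell markers Bst2 (0.41) and Clec9a (1.40) were higher, the latter lost in 7 of 15 alternatives with adjusted p up to 0.1, and camera did not call that list (adjusted p = 0.14).

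Osteoclast markers were higher in 5 of 8 cases (median 1.55): Dcstamp, Mmp9, the acid phosphatase Acp5 (1.90), the proton pump subunit Atp6v0d2 (285 ± 50.2 against 125 ± 24.4 CPM, 1.19) and Ocstamp (1.91; named after its value was seen; call lost without WT 24 h replicate 3, adjusted p = 0.061). Nfatc1, the transcription factor that drives osteoclast formation, was lower (-0.51). As a list the markers had camera adjusted p = 0.005, and adjusted p = 0.52 with an estimated correlation.

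NF-kB cytokines and regulators were higher in 9 of 24 cases (10 adjusted over the list alone; median 0.37), with Tnf at 12.4 ± 1.18 against 5 ± 0.561 CPM (1.30), Ccl5 at 1.85 and Nfkbiz at 0.64. The receptor gene Tlr2 (-0.70) and Icam1 (-0.24; named after its value was seen) were lower. Heat shock proteins were higher in 7 of 13 cases (median 0.11), among them Hsph1 (0.60), Hsp90aa1 (0.54) and Bag3 (0.48). Glycolysis and hypoxia genes were higher in 7 of 21 cases (9 adjusted over the list alone; median 0.12), with Pdk1 at 0.78, the glucose transporter Slc2a1 at 0.55 and Pfkp at 0.53, and Bnip3 was lower (-0.33; named after its value was seen; call lost without WT 24 h replicate 3, adjusted p = 0.057; 2 lower adjusted over the list alone). In this order camera gave adjusted p = 0.0061, 0.005 and 0.0061, and adjusted p = 0.52, adjusted p = 0.2 and adjusted p = 0.56 with an estimated correlation.

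Interferon-stimulated genes were higher in 5 of 28 cases, Irf7 (1.00), Isg15 (0.66), Oasl2 (0.50), Bst2 (0.41) and Mx2 (0.59), and Cxcl10 was lower (-0.65); Mx2 and Cxcl10 were named after their values were seen and lost their calls in 12 and 7 of 18 alternatives, with adjusted p up to 0.14 and 0.12, and Oasl2 without MKP5-KO replicate 1 or WT 24 h replicate 3, with adjusted p up to 0.053. Adjusted over the list alone 4 were higher. Camera called the list (adjusted p = 0.0078, and adjusted p = 1 with an estimated correlation); the call was lost without WT 24 h replicate 2 or MKP5-KO replicate 2, with adjusted p up to 0.27. Lysosome genes were higher in 7 of 23 cases, Gpnmb (0.68) and Ctss (0.70) among them, and Neu1, Npc1, Lamp1 and Lamp2 were lower (named after their values were seen; Lamp1 and Lamp2 lost their calls in 3 and 2 of 18 alternatives, with adjusted p up to 0.077 and 0.09; 5 lower adjusted over the list alone). The lysosome list had camera adjusted p = 0.034, and adjusted p = 1 with an estimated correlation; this call was lost with a replicate block and without WT 24 h replicate 2, MKP5-KO replicate 2 or MKP5-KO replicate 3, with adjusted p up to 0.09.

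Stromal fibroblast markers were lower in 9 of 11 cases (median -2.91, adjusted p = 5e-04, and adjusted p = 0.52 with an estimated correlation), and Pdgfra stood at 0.795 ± 0.511 against 0.51 ± 0.164 CPM. Col1a1 had 5.69, 6.91 and 1.21 CPM in the MKP5-KO libraries. Matrix remodelling genes went both ways, 9 of 24 higher and 12 lower (14 adjusted over the list alone): Mmp12 stood at 2051 ± 187 against 810 ± 147 CPM (1.35), the urokinase gene Plau was higher by 1.32 and its receptor gene Plaur by 0.72, while Sparc was lower. Camera did not call this list (adjusted p = 0.98). Of the neutrophil markers, Mmp8 was lower (-1.33) and 10 of 11 did not pass the test. Some of these had almost no reads in either group. MKP5-KO and WT at 24 h had 0 and 0 reads of Camp and of Elane, 1 and 2 of Ltf and 5 and 3 of S100a9. For such genes the count does not show that the genotypes were alike.

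Macrophage markers went both ways in MKP5-KO, with 6 of 15 higher (8 adjusted over the list alone) and Lyz2, Mertk, Maf, Cx3cr1 and Csf1r lower; the list had a median of 0.13, a mean of -0.08 and was not called (adjusted p = 0.45, direction up). Lyz2 stood at 5757 ± 476 against 10890 ± 1080 CPM (-0.92), Mertk at 81.1 ± 8.54 against 160 ± 15.9 CPM (-0.98), Maf at -0.79 and Cd14 at 0.60. Of 24 genes of cholesterol synthesis and LDL uptake, 3 were lower, Mvd (-0.47), Stard4 (-0.39) and Fdft1 (-0.35), and 21 did not pass the test (camera adjusted p = 0.98). Fdft1 lost its call without MKP5-KO replicate 2 or WT 24 h replicate 1, with adjusted p up to 0.057.

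Both comparisons share the WT 24 h libraries, and the overlap of their calls was set beside that of independent lists. Of the genes that rose in WT, 1402 were lower in MKP5-KO, 2.06 times the 681.6 such lists give, and 298 were higher, 0.63 times the 475.8 they give. Of those that fell, 845 were higher in MKP5-KO (1.74 times 486.8) and 406 lower (0.58 times 697.3). Itgal, Itga6 and Lyz2 rose by 3.46, 1.16 and 1.84 and were lower in MKP5-KO (-0.85, -0.87 and -0.92), as was the collagen chaperone Serpinh1 (3.79 and -3.10). Plk2, Myc, the potassium channel gene Kcnn4 and the kinase gene Map4k1 fell (-2.21, -3.01, -1.27 and -1.88) and were higher in MKP5-KO (1.53, 1.64, 1.17 and 0.94). Kcnn4 stood at 187, 77.7 and 175 CPM in WT at 0 h, WT at 24 h and MKP5-KO. Itgax (9.79, 112 and 411 CPM in the same order), Clec7a, which encodes the receptor dectin-1 (15.2, 153 and 319 CPM), Egr2 and Arhgap25 (1.13 and 1.30) rose and were higher still, and Pira2 (138, 41.1 and 14.6 CPM), Psmb5 (-0.73 and -0.90) and Gypc (-1.76 and -2.22) fell and were lower still. In opposite directions 2247 genes were called and in the same direction 704. Without WT 24 h replicate 2 these numbers were 1586 and 444.

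Across genes, which are not independent replicates, the fold changes had a Pearson r of -0.331 and a Spearman rho of -0.346, where 100 simulations of unchanged groups gave means of -0.503 and -0.449 from the shared controls alone. The covariance was -0.196 against a simulated mean of -0.032, a difference of -0.164. With the WT 24 h libraries divided 1 and 2 between the comparisons in all 6 ways, so that none was shared, the covariance lay between -0.184 and -0.144, Pearson r between -0.304 and -0.224 and Spearman rho between -0.318 and -0.231. Calls were not made with divided libraries, so the part of the opposite calls that comes from the shared controls is not known.

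**Figure D4:**
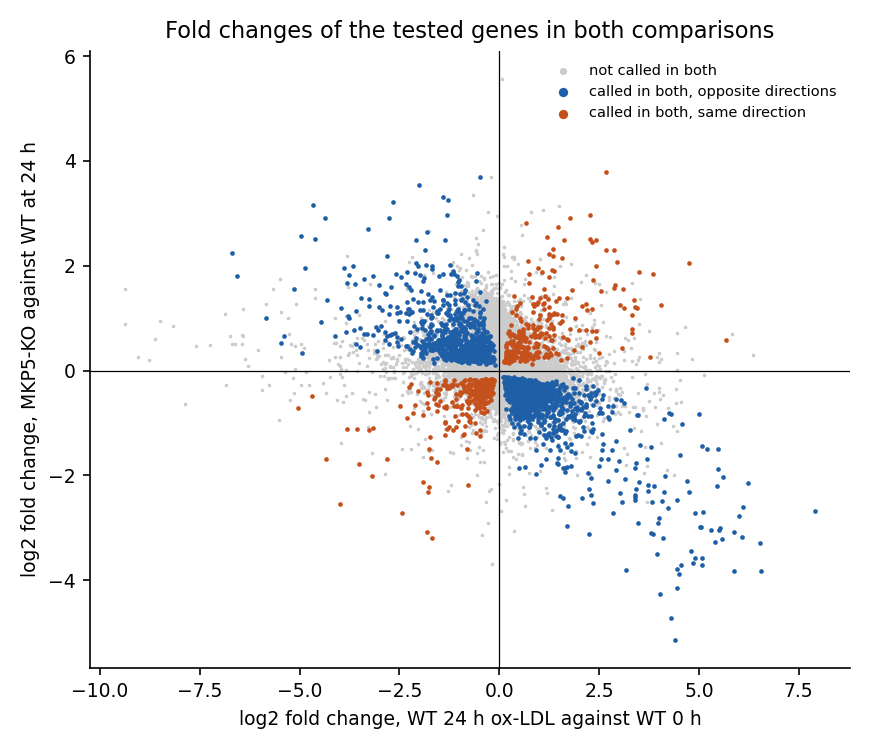
Each point is 1 of 14794 tested genes, with its log2 fold change for WT at 24 h against 0 h on the horizontal axis and for MKP5-KO against WT at 24 h on the vertical axis. The 2247 genes called in opposite directions are blue, the 704 called in the same direction orange and the rest grey.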

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

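The pseudocount and equal-depth settings were chosen after seeing the data. The DESeq2 alternatives, for gene counts and the overlap, were not run, although reads had been recovered. The alternative test on recovered reads was limma-voom. No gene called both in the main fit and in an alternative changed direction between them. Genes that lost their call were checked for direction only where they are named. Named genes that were rerun stayed on their side of the threshold in 4127 pairs of gene and setting and lost the call in 118, and none gained one. All the losses are of genes whose losses are given where they are named. Acta2, Pdgfra, Pdpn, Thy1, Runx2 and Fap for ox-LDL were not rerun. Nor were Ciita, Pdgfra, Camp, Elane, Ltf and S100a9 in MKP5-KO, or the sex-linked genes. Requiring a 2-fold change left 2514 ox-LDL calls (1339 higher, 1175 lower) and 821 MKP5 calls (564 and 257). An adjusted p under 0.01 left 1979 MKP5 calls (838 higher, 1141 lower), 1117 genes in opposite and 295 in the same direction in both comparisons. Leaving out each library in turn, genes lower in MKP5-KO ranged from 1637 to 2418 and genes higher from 1186 to 1641. Same-direction genes ranged from 444 to 689 and opposite-direction genes from 1582 to 2075. The lowest values came without WT 24 h replicate 2, except for opposite-direction genes, which were fewest without replicate 3 of that group. Without that replicate 3, 1655 genes were lower. These settings have fewer samples. With an estimated correlation 0 and 0 gene lists passed, where 16 and 9 did with the preset one, and fry called 27 and 8, in MKP5-KO without the interferon-stimulated and lysosome lists (adjusted p = 0.34 and 0.079) and with MAP kinase pathway components, lower (adjusted p = 0.016). Same-number samples of different groups correlated between -0.02 and 0.19 in their deviations, and different-number samples between -0.168 and 0.122. The highest values, 0.19 and 0.142, joined MKP5-KO replicate 1 with replicate 1 of WT at 0 h and at 24 h. Only 2 of 9 samples matched their own number best in both other groups. A pairing of some samples by replicate number therefore stays open. With the number as a replicate block 8236 genes were called for ox-LDL and 4382 for MKP5 deletion, and of the gene lists the call of the lysosome list in MKP5-KO was lost. Depth limits the genes with few reads: 224 tested genes had no reads in at least 1 library.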

Other observations

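The dendritic share, chromosome segment and stromal share tests below were fixed before their results were seen; the equal-depth, shared-control, single-library and MKP5-KO replicate 1 tests and the division of the cell cycle list were chosen after.

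Cell cycle genes split by phase, in opposite ways in the comparisons. In WT after 24 h 12 of 13 genes of DNA replication and the G1/S transition fell and none rose (median -1.19), among them the helicase subunit Mcm2 (103 ± 1.8 to 27.9 ± 5.87 CPM, -1.90), the licensing factor Cdc6 (-1.92) and E2f1 (-0.82), while 14 of 15 genes of G2 and mitosis rose (median 0.59), with the cyclin Ccnb2 from 44.9 ± 0.866 to 111 ± 14.7 CPM (1.30). In MKP5-KO 11 of 13 replication genes were higher than in WT (median 0.68; Pcna 303 ± 16.4 against 154 ± 30.8 CPM, 0.99) and 14 of 15 mitotic genes lower (median -0.72; Ccnb2 -1.27, Ccnb1 -1.01, Cdc20 -0.85). WT 24 h replicate 3 stood apart, with a mean log2 deviation of -1.01 for replication genes (-0.34 and -0.51 in replicates 1 and 2) and 0.17 for mitotic genes (0.58 and 0.62). Without it the medians for replication and mitosis were -1 and 0.74 in WT and 0.46 and -0.84 in MKP5-KO, with 12 lower, 15 higher, 11 higher and 15 lower. The undivided list, with 14 higher and 12 lower for ox-LDL (13 lower adjusted over the list alone) and 11 and 14 for MKP5 deletion (15 lower adjusted over the list alone), was not called by camera (adjusted p = 0.96 and 0.93). Its median for ox-LDL was 0.37 and its mean -0.19.

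Genes of lipid uptake and storage also differed in MKP5-KO without a direction as a group. Lipoprotein lipase, Lpl, stood at 5120 ± 451 against 1953 ± 354 CPM in WT at 24 h (1.40), the fatty acid and ox-LDL receptor Cd36 at 3211 ± 321 against 1756 ± 224 CPM (0.87), and the nuclear receptors Pparg at 56.4 ± 3.98 against 23.3 ± 2.98 CPM (1.28) and Nr1h3, LXR alpha, at 18.4 ± 0.157 against 7.2 ± 1.44 CPM (1.37); the exporter Abcg1 was higher by 0.49. Ppard (-0.58) and the scavenger receptor Stab1 (1216 ± 194 against 2339 ± 338 CPM, -0.95) were lower. Among efferocytosis genes Axl (273 ± 26.2 against 114 ± 7.11 CPM, 1.26) and Anxa1 (1003 ± 59.3 against 419 ± 49 CPM, 1.26) were higher and Mertk lower. In the lipid storage list 5 of 20 genes were higher, Pparg, Lpl, Lipa, Plin2 and Hilpda, and 4 lower, among them Ppard, Fabp5 and Cpt1a (6 and 7 adjusted over the list alone). Of 14 scavenger receptors Cd36, Cd68 and Msr1 were higher (4 adjusted over the list alone) and Stab1, Scarb2 and Scarf1 lower. Of 12 cholesterol efflux genes Nr1h3, Abcg1, Scd2 and Pltp were higher and Arl4c, Smpdl3a, Abca1, Mylip and Apoe lower, the same numbers as adjusted over the list alone. Of 19 efferocytosis genes Axl, Anxa1 and Tyro3 were higher (5 adjusted over the list alone) and 6 lower. Camera called none of these lists (adjusted p = 0.93, 0.99, 0.93 and 0.99), and in each the median, the mean and camera's direction did not share a sign. Genes given here without a value, Lipa, Cd68, Scarb2, Scd2 and Arl4c aside, were chosen after their values were seen; Hilpda, Cpt1a, Pltp, Abca1, Mylip, Apoe and Tyro3 lost their calls in 4 to 12 of 18 alternatives, with adjusted p up to 0.44.

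Stromal markers rose in WT at 24 h and were lower in MKP5-KO, and a share of stromal cells is a candidate explanation. For a larger share at 24 h, a second list of fibroblast lineage genes that code for no matrix protein was called higher in 71.4% of 14 tested members (median 1.89), the level set for this explanation beforehand. In that list Pdpn fell (-1.40), and Thy1 (-0.11), Runx2 (0.21) and Fap (1.24) did not pass the test. Of 15 further matrix genes 15 rose. For a smaller share in MKP5-KO the lineage list was lower in 35.7% (median -0.78), between the levels set for and against it, while 13 of 15 further matrix genes were lower and none higher (median -2.6). In the lineage list Tagln (-2.38), Myl9 (-2.20) and Cald1 (-2.25) were lower but Thy1 (0.85; call lost without WT 24 h replicate 2, adjusted p = 0.055), Pdpn (1.35) and Tpm1 (0.54) higher. Dcn had 24, 16 and 27 reads and Lum 2, 2 and 3 in WT at 0 h, WT at 24 h and MKP5-KO, which argues against fibroblasts rich in these transcripts and leaves open other stromal cells, or matrix genes expressed by the macrophages, which was not tested. Lower depth is argued against: at equal depth the median for MKP5-KO was -2.76.

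Genes that changed in WT over 24 h with ox-LDL tended to differ the other way in MKP5-KO. Of the 8189 called in WT, 2247 were called the other way in MKP5-KO and 704 the same way. Most were not called there. The shared WT 24 h libraries alone are argued against by the covariance of -0.196, below the simulated range of -0.0349 to -0.029, and by a covariance of -0.184 to -0.144 with no WT 24 h library in both comparisons, a division added after the data were seen. Pearson r and Spearman rho (-0.331 and -0.346) were less negative than in the simulations (-0.535 to -0.467 and -0.468 to -0.434). A correlation is divided by the spread of the fold changes, which in unchanged groups is noise alone, so the covariance and the divided libraries carry this argument. If the replicates are repeats of 1 culture, dividing them does not remove what they share. That 1 library alone carries the relation is argued against by the value nearest 0 without any 1 WT 24 h library, -0.17. A weaker response to ox-LDL, or to time in culture, without MKP5 stays open as a hypothesis. Without untreated WT cells at 24 h these cannot be set apart, and without MKP5-KO cells at 0 h neither can be set apart from a difference that was there before ox-LDL.

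MHC class II genes were higher in MKP5-KO. Of 8 tested MHC class II genes 0 lie on the chromosome of Dusp10, so a chromosome segment carried along with the deleted gene does not contain them. Gene positions do not depend on these data, and an effect of such a segment on genes elsewhere was not tested and stays open. Within 20 Mb of Dusp10 80 of 228 tested genes were called (35.1%) and elsewhere 28.7% of 13987 (odds ratio 1.34, two-sided p = 0.0387, Fisher's exact test). MKP5-KO replicate 1 alone is argued against by a list median of 0.59 without it. A larger share of dendritic cells stays open: 2 of 5 tested members of a second dendritic cell list with low levels in WT were higher and none lower (median 0.04), and reads in WT at 24 h and MKP5-KO were 5 and 3 for Flt3, 38 and 18 for Zbtb46 and 9 and 5 for Siglech, but 0 and 21 for Cd209a, 0 and 2 for Ccr7 and 0 and 1 for Xcr1. A direct effect of MKP5 loss on class II transcription was not tested.

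Each comparison allows 10 splits of its 6 libraries, too few for a share under 0.05, and 1 of 10, the real one, gave as many calls in each. The real splits called 8189 and 4230 genes and the highest other split called 0 in both with limma, with 213 and 879 genes at an unadjusted p under 0.05 and 0 and 0 called by limma-voom. Each other split mixes the groups compared, so a real difference between them widens the spread within its groups and keeps calls few. The contrast with the real splits therefore decides nothing. Xist had 2 reads in WT 24 h replicate 1 and 39 to 90 in the other libraries. It stood at 2.81 ± 0.914, 1.45 ± 1.24 and 5.26 ± 1.18 CPM in WT at 0 h, WT at 24 h and MKP5-KO. In the same order the Y-linked gene Ddx3y stood at 64.4 ± 2.36, 83.3 ± 6.64 and 73.7 ± 3.96 CPM and Kdm5d at 27 ± 3.24, 40.8 ± 2.97 and 30.7 ± 1.99 CPM. Of 5 tested sex-linked genes 4 were called higher and 0 lower for ox-LDL, and 0 higher and 1 lower in MKP5-KO. Whether the groups differed in their mix of sexes was not tested.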
